A study of Dendrobium nobile with 12 samples.

How the data were processed

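Messenger RNA was measured by RNA-seq in 6 tissues of the orchid Dendrobium nobile, with 2 libraries per tissue. The labels give root, stem and leaf from 1-year seedlings, and bud, petal and labellum (the lip, the modified petal of an orchid flower) from 2-year seedlings. One cultivar grown in a greenhouse was used for the 12 libraries. The series title names D. nobile and its picrotoxane-type alkaloids, while its design text names D. officinale; the organism label of every library is D. nobile, and that name is used here. The labels say bud without saying of which kind, and bud was placed with the floral tissues before the data were examined. They give no flower stage for petal and labellum, which are called open floral organs here for short. Organ class and seedling age change together in this design and cannot be told apart. No label says that the 2 libraries of a tissue came from separate plants, so the p-values measure the spread between these libraries, which may be technical.

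Per the labels' protocols, total RNA was extracted with a column kit (Qiagen), and libraries were made with a SMARTER mRNA-seq kit. The aligner, the counting program, its handling of strand and of reads with several matches, and the genome build behind the gene models are not given in the sources used here. The submitters' processing notes name the mouse builds GRCm38 and mm10. The identifiers, in contrast, are gene models numbered along 19 chromosomes (31452 models) and 10 scaffolds (220 models), and are used exactly as deposited. Without a stated counting rule, values of near-identical neighbouring models, overlapping models and antisense models are uncertain.

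The authors deposited a table of read counts per gene model, whole numbers that were not normalised, for 31672 models in the 12 libraries. They also deposited a table of FPKM values (fragments scaled by gene length and library total) for the same models and libraries. Each FPKM above 0 equalled the deposited count divided by one length per model and by the library's total count, in 100% of 224365 values with a tolerance of 0.01 bp. Those lengths were multiples of 3 in 100% of the 22389 models with a count, so they are called coding lengths here; their median was 1101 bp and their range 153 to 16149 bp. The deposited tables pair no identifier with a gene name or product, and no reference genome or annotation was used here. For this reason 17 lists of gene products fixed before the data were examined (terpenoid precursor pathways, terpene synthases, photosynthesis, floral MADS-box genes, pollen markers and others) were not tested, and no function is stated for any model.

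Counts were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test, after filterByExpr and TMM scaling, in one model with a mean for each tissue. The 12 libraries left 6 residual degrees of freedom, and 19123 models (60.4% of all) were tested; 9283 models had a count of 0 in every library. A model was called when its Benjamini-Hochberg adjusted p was under 0.05 and its change was at least 2-fold. The comparisons were floral against vegetative tissues (3 tissues each, tissues weighted equally), bud against the 2 open floral organs, labellum against petal, stem against leaf, stem against root and leaf against root, together with one test for any difference among the 6 tissues. A model was called enriched in a tissue when it passed both thresholds against each of the 5 other tissues in the higher direction, and depleted when it did so in the lower direction (given for root alone, since the sets of the other tissues moved with single libraries). Standard errors of log2 fold changes are the fold change divided by the square root of the F statistic. Where the lower group has few counts they are approximate and can understate the uncertainty. Levels are given as mean FPKM ± SD over libraries. Tissue specificity was measured by tau on log2(FPKM + 1), which is 0 for a model equal in all tissues and 1 for a model present in a single tissue, over models with an FPKM of at least 1 in both libraries of a tissue.

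Named models follow a rule fixed before the data were examined. For each comparison they are the 2 called models per direction, or 1 per tissue for the enriched sets, with the largest fold change among those with an average log2 CPM of at least 3 and no overlap between the libraries compared; for an enriched set the fold is the smallest of the 5 pairwise folds. Where the lower group had a count of 0, the fold is a lower bound against a floor of 3 counts over that group. Where it had 1 to 3 counts, the ratio of pooled CPM is given with a 95% interval from the exact Poisson limits of that count. The ratio of pooled CPM also stands in place of a fitted fold for floral against vegetative tissues, where each named model had 0 counts in at least 1 tissue and the fitted fold there rests on a prior count. Floors and intervals cover counting error only, since PCR copies are not independent molecules.

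The test was tried on simulated counts for the 19123 models, drawn from the measured means and library sizes, with 200 models changed. Each model had one spread shared by all 12 libraries, and models with a low mean were not among those changed. The shares called therefore do not describe tissues at their own spread or models of low level. For stem against leaf, 12% of models changed 2-fold, 68% changed 4-fold, 78% changed 8-fold and 98% changed 16-fold were called, and 10 unchanged models were called. For floral against vegetative tissues these shares were 40%, 94%, 100% and 100%, with 5 unchanged models called. For enrichment in root they were 0%, 54%, 82% and 92%, with 0 unchanged models called. With no model changed and each tissue given its own measured spread, the test called 216 models higher and 267 lower for bud against the open floral organs, and 0 models in each of the other 5 comparisons.

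Alternatives fixed before the data were examined were DESeq2 size factors, total counts without TMM, no low-count filter, DESeq2 1.42.0 as the tool, limma 3.58.1 on log2(FPKM + 1), the replicate number as a block, an adjusted p of 0.01, no fold minimum, a fit of the compared tissues alone, and each library left out in turn. Added after seeing the data were limma-voom with a variance weight per tissue, removal of each library's trend with coding length, and fits without both bud or both root libraries. Correlations, tau and permutations were computed in Python 3.11.15 with scipy 1.17.1.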

Results

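The 12 libraries profile 6 tissues of the orchid Dendrobium nobile, 3 of them vegetative (root, stem and leaf) and 3 floral (bud, petal and labellum), with 2 libraries each. The series belongs to a genome study concerned with how this species makes and stores sesquiterpenoid alkaloids of the picrotoxane type, and the tissues show where each gene model is transcribed. Total counts per library were 14165136 and 5289212 for root, 28699617 and 27175842 for stem, and 32040196 and 31341240 for leaf. They were 27307456 and 30450170 for bud, 30860097 and 28355940 for petal, and 28863056 and 30188499 for labellum. Root replicate 2 was the shallowest library.

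Petal and labellum had the most similar transcriptomes, and stem and leaf followed. Spearman's rho across the tested models averaged 0.960 between petal and labellum libraries, 0.915 between stem and leaf, 0.899 between bud and petal, and 0.889 between bud and labellum. Root was about as far from stem (0.765) and leaf (0.732) as those were from the floral tissues (0.723 for leaf and bud to 0.787 for stem and labellum), and its rho with floral tissues ran from 0.673 with bud to 0.768 with labellum. Each of the 12 libraries had its highest rho with the other library of its own tissue. The first principal component of log2 CPM, 40.7% of the variance, separated the floral from the vegetative libraries, and the second, 29.7%, set root apart from stem and leaf. The 100 most abundant models of petal and labellum shared 69 members, and those of stem and leaf shared 50. These are correlations across genes, which are not independent replicates.

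**Figure D1:**
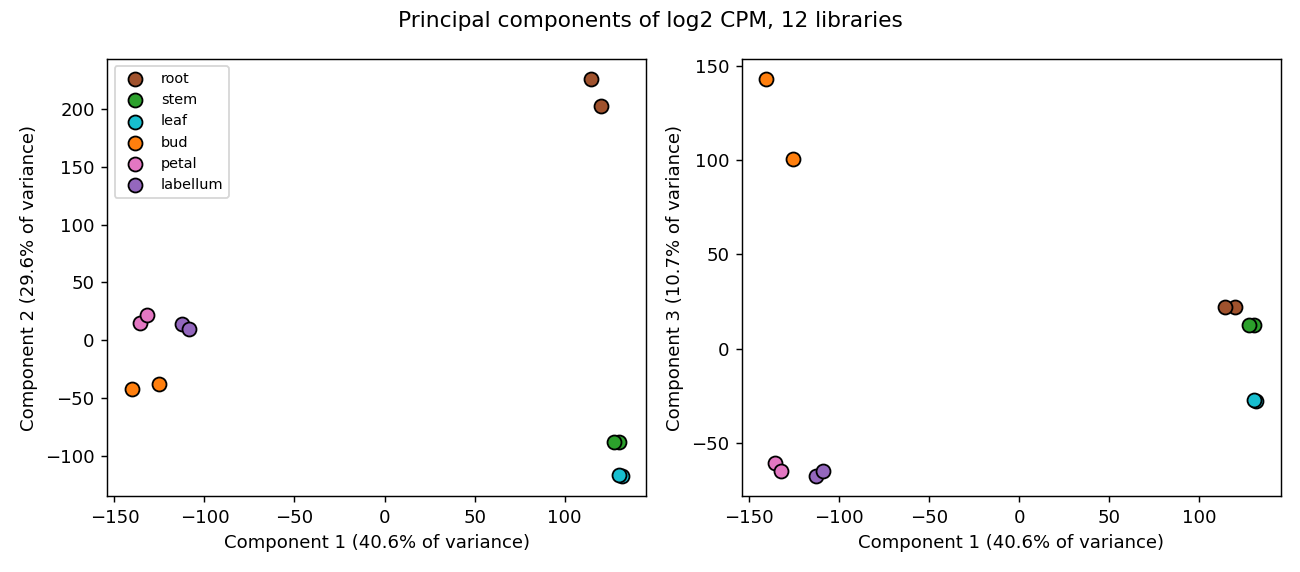
Principal components of log2 CPM, one point per library, with 2 libraries for each of 6 tissues; the axes are component scores with their percent of variance. Floral and vegetative libraries lie on opposite sides of component 1 (40.7%), root is apart on component 2 (29.7%), and bud is apart on component 3 (10.7%).

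Replicates were close in stem and leaf and farther apart in bud. The biological coefficient of variation between the 2 libraries was 0.072 in leaf, 0.076 in stem, 0.194 in petal, 0.295 in labellum, 0.357 in root and 0.579 in bud. In bud 1875 tested models differed at least 4-fold between replicates, against 151 in leaf. The 2 libraries of every tissue differed by more than the counting noise of independent reads, with a chi-square per degree of freedom between 4.56 in leaf and 219 in bud, which PCR copies or a second preparation of the same RNA would give as well. Replicate 2 of bud was closest to replicate 1 of bud by a narrow margin, with a rho of 0.925 against 0.921 with petal replicate 1.

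Most expressed models varied among the tissues. In a single test for any difference among the 6 tissues, 15527 of 19123 models passed an adjusted p of 0.05. Their highest mean was in root for 3490 models (22.5%), in leaf for 3170 (20.4%), in bud for 2929 (18.9%), in petal for 2485 (16%), in stem for 2228 (14.3%) and in labellum for 1225 (7.89%). Between pairs of tissues, called models were fewest between petal and labellum (719) and most numerous between root and bud (9940).

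Expression was broad for most models and narrow for a minority found mainly in root and bud. Stem expressed the largest number of models at an FPKM of at least 1 in both libraries (15566), followed by leaf (15074), bud (14664), labellum (14267), root (14250) and petal (14165). Of the 17757 models that reached this level in at least 1 tissue, 11654 did so in all 6, 174 in the 3 floral tissues and in no vegetative one, and 364 in the 3 vegetative tissues and in no floral one. Models that reached it in a single tissue numbered 454 in bud, 445 in root, 304 in stem, 217 in leaf, 62 in petal and 45 in labellum. Tau was at least 0.8 for 1353 models (7.62%), of which 451 peaked in root, 433 in bud, 255 in stem, 160 in leaf, 36 in labellum and 18 in petal; the number depends on the scale, and was 826 with a pseudocount of 0.1, 2257 with an FPKM filter of 0.1 and 3625 on linear FPKM. Tau was under 0.3 for 9230 models (52.0%). The order of the tissues by models detected changed with the threshold. At an FPKM of at least 0.1 in both libraries, bud (17434) passed leaf (17415) and root (16341) was lowest, while stem (17883) stayed highest.

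The same short model, evm.model.Chr12.691-gene (coding length 363 bp, chromosome 12), was the most abundant transcript in all 6 floral libraries; it is outside the naming rule and was chosen after its values were seen. It took 4.63% ± 0.741 of counts in bud, 2.15% ± 0.286 in petal and 2.39% ± 0.0940 in labellum (mean ± SD, n = 2 each). In leaf it took 0.415% ± 0.00148, in stem 0.171% ± 0.00156 and in root 0.00592% ± 0.00302 of counts (n = 2 each).

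Root had the most enriched models, and they made up a large part of its messenger RNA. In root 1134 models were higher than in each of the 5 other tissues, 467 of them by at least 8-fold, and 314 were under an FPKM of 1 in all 5 others. These models took 20.9% ± 0.849 of root counts (n = 2). Leaf had 750 enriched models, which took 24.7% ± 0.00707 of its counts but were less exclusive, since 81 were at least 8-fold higher and 605 were next highest in stem. Stem had 302 enriched models, 118 of them at least 8-fold higher, which took 9.34% ± 0.00849 of its counts. Depleted models numbered 1561 in root.

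The model named for root, evm.model.Chr14.529-gene on chromosome 14, stood at 146 ± 75.1 FPKM in root (n = 2) and at 1 count in the petal libraries, a ratio of 16700 with a 95% counting interval of 2990 to 658000 (9100 without root replicate 1, 7980 without petal replicate 1, and at least 2890 without petal replicate 2, which held the count). In stem, evm.model.Chr15.1200-gene reached 706 ± 6.24 FPKM, against 0.659 ± 0.189 in bud (n = 2 each), a log2 fold change of 9.80 ± 0.80 (SE). In leaf, evm.model.Chr17.2152-gene reached 208 ± 4.33 FPKM, against 0.330 ± 0.147 in stem (n = 2 each), a log2 fold change of 9.48 ± 0.59. Their adjusted p values in these smallest of 5 pairwise differences were 4.62e-05, 9.48e-06 and 2.34e-05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). The stem set was 564 models by limma on log2(FPKM + 1), and it fell to 177, 170, 186 and 192 models without stem replicate 1, stem replicate 2, leaf replicate 1 and leaf replicate 2, from 302. The leaf set, 750 models with all libraries, fell to 430, 412, 468 and 464 without the same libraries in turn.

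Bud had the largest set of enriched models among the floral tissues, while petal and labellum each had few models of their own. In bud 628 models were enriched, 362 of them at least 8-fold, and 307 were under an FPKM of 1 in the 5 other tissues; they took 4.22% ± 0.954 of bud counts (n = 2). Petal had 42 enriched models, none of them 8-fold higher than in every other tissue, and labellum had 41, of which 10 were at least 8-fold higher. Median coding lengths were 804 bp for the bud set, 919.5 bp for petal and 1470 bp for labellum, against 1134 bp for all tested models.

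In bud, evm.model.Chr09.138-gene (chromosome 9) stood at 122 ± 49.9 FPKM (n = 2) and at 1 count in the labellum libraries, a ratio of 5330 with a 95% counting interval of 957 to 211000 (2610 without labellum replicate 2, and at least 909 without labellum replicate 1, which held the count). In labellum, evm.model.Chr10.562-gene (chromosome 10) stood at 281 ± 135 FPKM, against 29.9 ± 11.98 in bud (n = 2 each), a log2 fold change of 3.33 ± 0.40 (SE), or 2.71 without labellum replicate 2. Their adjusted p values were 0.000493 and 0.00051 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). In petal, evm.model.Chr16.1509-gene (chromosome 16) stood at 241 ± 115 FPKM, against 39.2 ± 20.3 in labellum (n = 2 each), a log2 fold change of 2.71 ± 0.60. That fold was 3.40 without labellum replicate 2, 2.25 without labellum replicate 1 and 2.15 without petal replicate 2. Its adjusted p was 0.0323 by the same edgeR test with Benjamini-Hochberg adjustment, and it did not pass the threshold in 9 alternatives, with an adjusted p of up to 0.196 without petal replicate 2.

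The sizes of the floral sets moved when single libraries were left out, those of other tissues among them. All tissues share one estimate of spread in the fit. Bud's 628 models became 338 without petal replicate 1 and 287 without petal replicate 2. Petal's 42 became 80 and 110 without bud replicates 1 and 2, 20 without either stem library, 14 and 6 without petal replicates 1 and 2, and 23 and 15 without labellum replicates 1 and 2. Labellum's 41 became 77 and 66 without bud replicates 1 and 2, 17 and 16 without petal replicates 1 and 2, and 27 and 19 without labellum replicates 1 and 2.

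**Figure D2:**
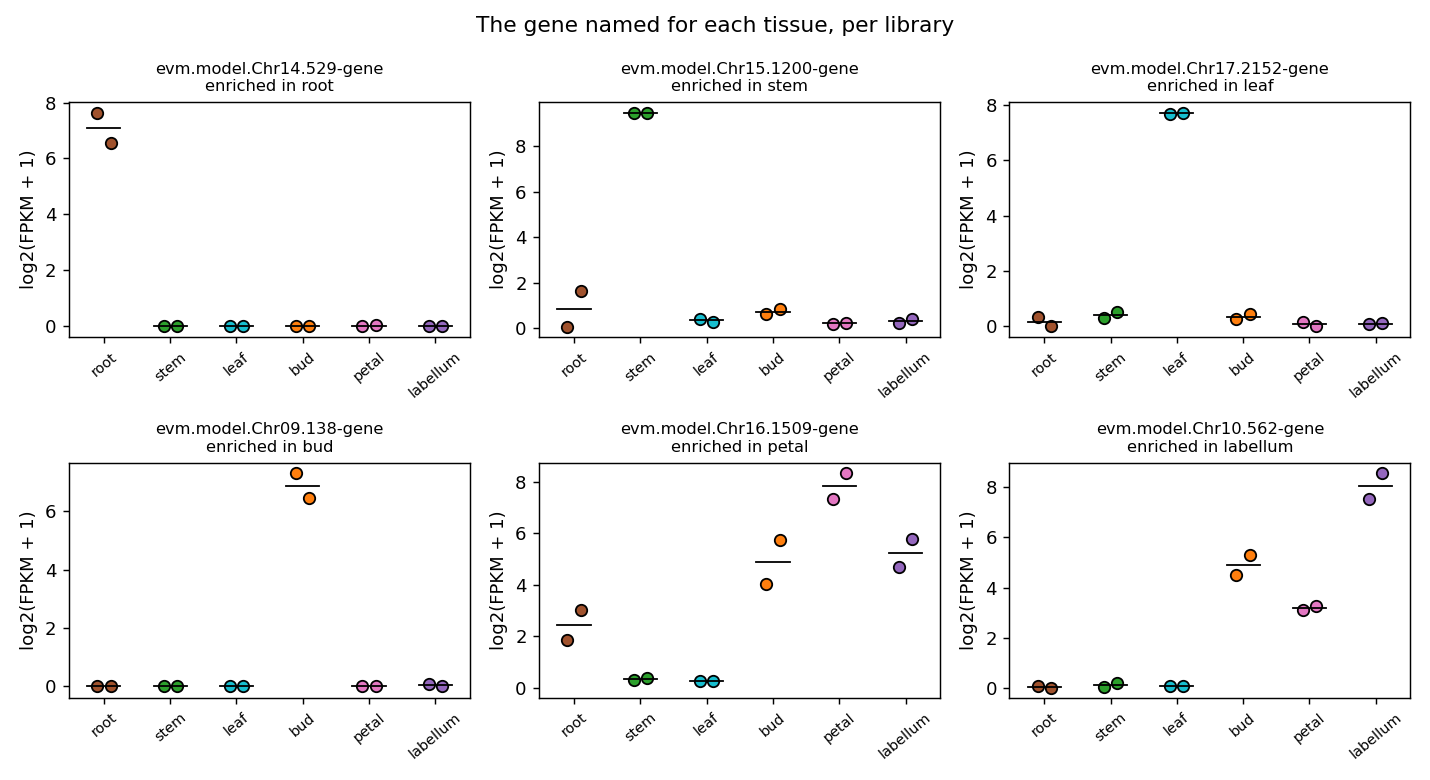
Level of the model named for each of the 6 tissues, as log2(FPKM + 1) on the vertical axis, for 2 libraries in each tissue; points are libraries and bars are tissue means. The models named for root, stem, leaf and bud stand far above the other 5 tissues in both libraries, while those named for petal and labellum are also present in other floral tissues.

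Floral and vegetative tissues differed in nearly as many models in each direction. Of the tested models 4597 were higher and 4014 lower in the floral tissues, together 45.0%, and 1358 and 892 of them changed at least 8-fold. The 6 floral libraries all lay above the 6 vegetative ones for 2335 of the higher models. They all lay below for 1890 of the lower ones. The other calls rest on class means with overlapping libraries, so a single tissue can carry them. The short model evm.model.Chr18.1295-gene (246 bp, chromosome 18) was at 756 ± 262 FPKM in the 6 floral libraries and at 0.234 ± 0.277 in the 6 vegetative ones, a ratio of pooled CPM of 2610 (4190 without stem replicate 2 and 2300 without stem replicate 1). Likewise evm.model.Chr08.94-gene (360 bp, chromosome 8) was at 173 ± 77.3 against 0.0722 ± 0.177 FPKM, a ratio of 1740, or at least 2230 without leaf replicate 1, which held all of its vegetative counts. Without leaf replicate 2 that ratio was 1350. In the other direction, evm.model.Chr07.1175-gene (783 bp, chromosome 7) was at 0.0729 ± 0.0825 FPKM in floral and 73.8 ± 45.2 in vegetative libraries, where it was higher by a ratio of 1210 (2030 without labellum replicate 1 and 1000 without bud replicate 2).

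The vegetative model evm.model.Chr17.352-gene (2829 bp, chromosome 17) was at 14.3 ± 13.8 FPKM in the 6 vegetative libraries and had 2 counts in the 6 floral ones, a ratio of 4640 with a 95% counting interval of 1280 to 38300 (7840 without bud replicate 1, 7750 without labellum replicate 1 and 3650 without leaf replicate 1). Its mean was 31.5 FPKM in leaf, 10.1 in stem and 1.41 in root. The adjusted p values of the models named for this comparison lay between 1.13e-08 and 2.54e-07 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). These p values, and the calls, rest on the spread between the libraries of a tissue. Differences among the tissues of a class do not enter that spread. The p values therefore cover these libraries and do not test floral and vegetative tissues in general. Likewise, the 6 libraries of a class are not 6 independent tissues. With total counts in place of TMM scaling the median log2 fold change of all tested models moved from 0.05 to -0.19, and the higher share of the calls went from 53.4% to 43.3%; it was 43.3% also on log2(FPKM + 1). The balance of higher and lower calls is therefore relative to the scaling.

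**Figure D3:**
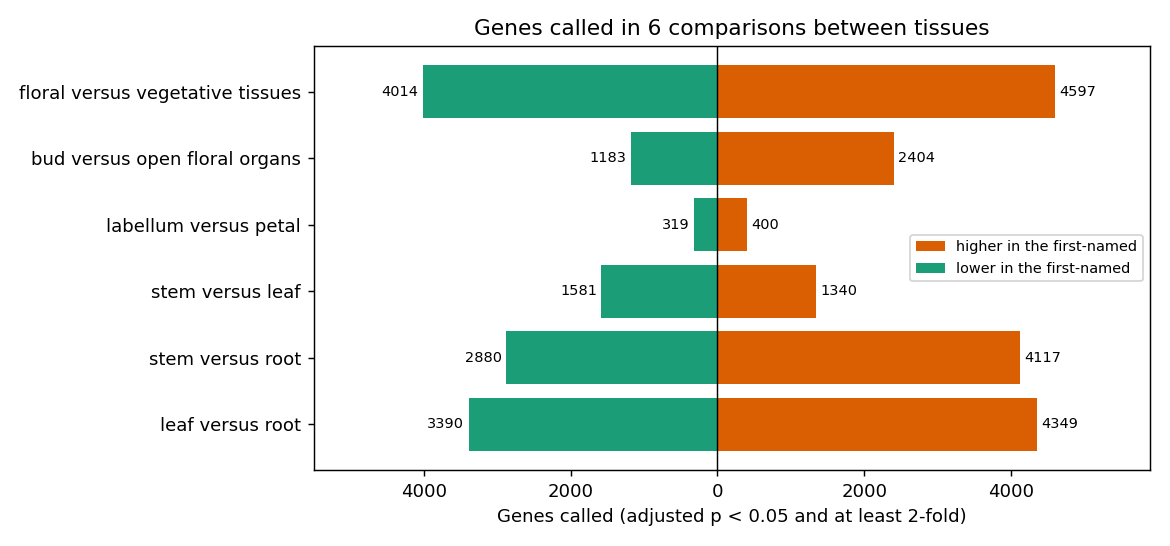
Number of models called in each of 6 comparisons (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold), with models higher in the first-named tissue to the right and lower ones to the left of 0. Floral against vegetative tissues gave 4597 and 4014 models, and labellum against petal gave 400 and 319.

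Coding length moved with this comparison. Models higher in floral tissues had a median coding length of 777 bp, those higher in vegetative tissues 1572 bp, and all tested models 1134 bp. With the models in 5 classes of length with nearly equal numbers, from the shortest (153 to 606 bp) to the longest (1896 to 16149 bp), the median floral minus vegetative log2 fold change was 1.00, 0.52, 0.14, -0.27 and -0.82. In the shortest class 1670 models were higher and 396 lower in floral tissues, and in the longest 308 were higher and 1539 lower. Across the 19123 models Spearman's rho of log2 fold change with coding length was -0.350. Models under 600 bp took 31.4% ± 1.19 of counts in bud, 27.0% ± 0.516 in petal and 23.0% ± 0.509 in labellum, against 15.2% ± 0.587 in root and 15.3% ± 0.00707 in stem (mean ± SD, n = 2 each), and 15.0% in each leaf library. With each library's trend with length removed, 3686 models were higher and 3343 lower, of which 3246 and 2800 had also been called without that step. In simulated counts where a trend with length was the only change, this comparison called 1095 models, and 0 after the trend was removed. Some of the calls can therefore come from such a trend alone. The simulated trend had a set size that was not fitted to these libraries.

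**Figure D4:**
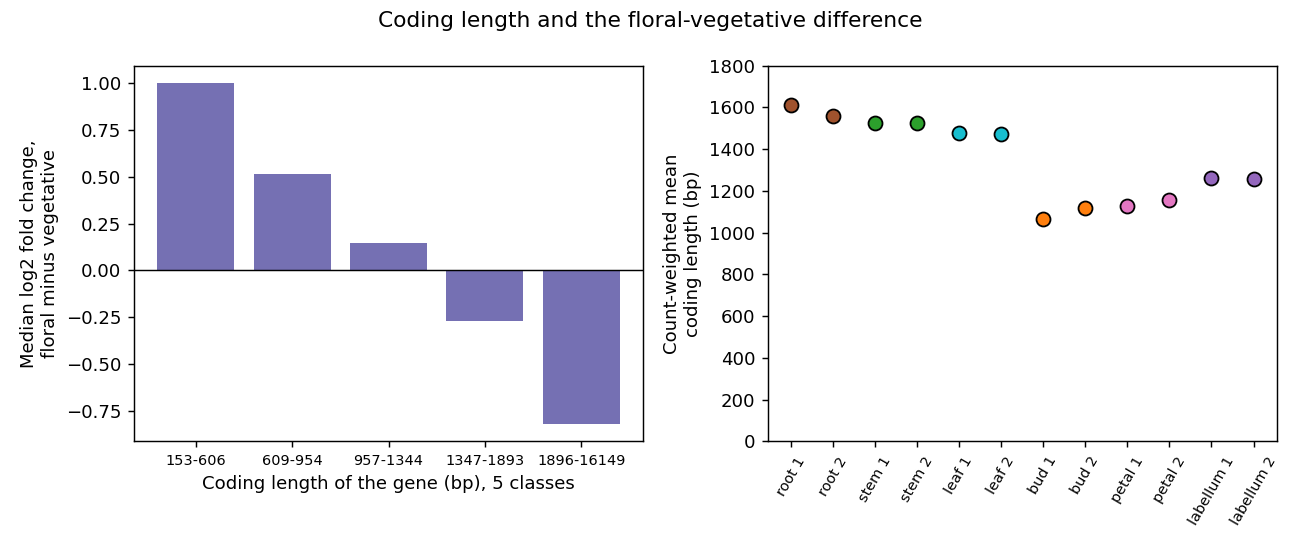
Left, median floral minus vegetative log2 fold change (vertical axis) for tested models in 5 classes of coding length in bp; right, count-weighted mean coding length in bp of each of the 12 libraries, coloured by tissue. The median falls from 1.00 in the shortest class to -0.82 in the longest, and the floral libraries lie at 1067 to 1260 bp against 1472 to 1610 bp for the vegetative ones.

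More models were higher than lower in bud against the open floral organs. Called models numbered 2404 higher and 1183 lower in bud than in petal and labellum together, and 994 against 111 of them changed at least 8-fold. In the 4 petal and labellum libraries evm.model.Chr03.709-gene (chromosome 3) and evm.model.Chr17.265-gene (chromosome 17) had 0 counts, and in bud they stood at 131 ± 104 and 86.4 ± 1.07 FPKM (n = 2 each). They were at least 2910-fold and at least 2050-fold higher in bud, the first at least 1320-fold without bud replicate 1 and at least 4690-fold without bud replicate 2. Conversely, evm.model.Chr17.673-gene was at 888 ± 297 FPKM in the open organs (n = 4) and 2.69 ± 2.73 in bud (n = 2), a log2 fold change of -8.47 ± 0.90 (SE), and evm.model.Chr06.2196-gene at 31.0 ± 8.98 against 0.232 ± 0.143, a log2 fold change of -7.15 ± 0.63. Without bud replicates 1 and 2 in turn these folds were -7.73 and -10.17 for the first and -8.04 and -6.55 for the second.

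Adjusted p values of these models were 0.000178, 0.000249, 0.000183 and 7.11e-05 in that order (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Here too the p values rest on the spread between the libraries of a tissue, and differences between petal and labellum do not enter it. In simulated counts with no model changed and the measured spread of each tissue, the same test called 216 models higher and 267 lower in this comparison. Limma-voom with a variance weight per tissue, added after seeing the data, called 1492 higher and 631 lower, and without bud replicate 2 the counts were 3016 higher and 2568 lower, against 2404 and 1183 with all libraries. With total counts in place of TMM the median log2 fold change of all tested models moved from 0.03 to 0.17. Median coding length was 990 bp for the models higher in bud and 1401 bp for the lower ones, and rho of log2 fold change with length was -0.191.

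Labellum and petal differed in few models. Called models numbered 400 higher and 319 lower in labellum, 3.76% of those tested. Of the models higher in labellum, evm.model.Chr15.1314-gene (chromosome 15) was at 294 ± 200 FPKM against 0.0546 ± 0.0771 in petal, a log2 fold change of 12.25 ± 1.02 (SE), and evm.model.Chr10.559-gene (chromosome 10) at 108 ± 50.03 against 0.0926 ± 0.131, a log2 fold change of 10.09 ± 0.99 (n = 2 each). These folds were 11.26 and 9.08 without petal replicate 1, and without petal replicate 2, which held all of their petal counts, the models were at least 3870-fold and at least 1700-fold higher; the first was 11.33 without labellum replicate 1 and the second 9.49 without labellum replicate 2. The petal libraries held 4 and 8 counts of these models. Without petal replicate 2 their fitted folds, which then rest on a prior count, were 16.39 and 15.19. The standard errors above therefore understate the uncertainty. In bud these models were at 60.1 and 12.2 FPKM. Of the models lower in labellum, evm.model.Chr11.1235-gene was at 2.22 ± 0.226 FPKM in petal and evm.model.Chr14.972-gene at 2.74 ± 0.547 (n = 2 each), each with 2 counts in labellum. Their ratios were 150 (95% counting interval 41.5 to 1240) and 95.2 (26.4 to 786). Each had its 2 counts in one library: the ratio of the first was 76.7 without labellum replicate 1 and at least 48.9 without labellum replicate 2, and that of the second 46.5 without labellum replicate 2 and at least 32.5 without labellum replicate 1. In stem evm.model.Chr14.972-gene was far more abundant, at 411 FPKM.

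In the order named, the adjusted p values were 0.000434, 0.00157, 0.00215 and 0.00215 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). The median coding length was 1414.5 bp for the models higher in labellum and 894 bp for the lower ones, with a rho of 0.271 between log2 fold change and length. With total counts in place of TMM the higher share of calls was 70.2% in place of 55.6%. The counts depended on which libraries shared the fit, with 610 higher and 494 lower when petal and labellum were fitted alone. Without bud replicates 1 and 2 in turn they were 831 and 827 higher and 714 and 708 lower. Without petal replicates 1 and 2 they were 99 and 78 higher and 86 and 61 lower, and without labellum replicates 1 and 2 they were 248 and 165 higher and 201 and 81 lower. Leaving out stem replicates 1 and 2 gave 241 and 243 higher and 151 and 150 lower, and leaving out leaf replicates 1 and 2 gave 232 and 229 higher and 176 and 175 lower.

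Stem and leaf, the closest vegetative tissues, differed in 1340 models higher and 1581 lower in stem, 15.3% of those tested. The stem models were more strongly changed, with 613 at least 8-fold higher in stem against 244 in leaf. A pair of neighbouring models of equal length on chromosome 15 led the stem side: evm.model.Chr15.1199-gene at 224 ± 5.79 FPKM against 0.0819 ± 0.0569 in leaf, and evm.model.Chr15.1200-gene at 706 ± 6.24 against 0.267 ± 0.0832 (n = 2 each), with log2 fold changes of 11.17 ± 0.77 and 11.16 ± 0.86 (SE). Another such pair on chromosome 9 led the leaf side. There evm.model.Chr09.410-gene was at 85.4 ± 1.54 FPKM in leaf with 2 counts in stem, a ratio of 2260 (95% counting interval 626 to 18700), and evm.model.Chr09.411-gene at 74.6 ± 11.1 against 0.0960 ± 0.0838, a log2 fold change of -9.72 ± 0.65. The ratio of pooled CPM of evm.model.Chr09.411-gene, 791 with all libraries, was 481 without stem replicate 1 and 2030 without stem replicate 2, where 1 count was left. That of evm.model.Chr15.1199-gene, 2720 with all libraries, was 5380 without leaf replicate 1, where 2 counts were left, and 1830 without leaf replicate 2.

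Within each pair the 2 models have the same coding length (1533 bp on chromosome 15 and 948 bp on chromosome 9), and reads shared between near-identical copies cannot be assigned without the sequences, so their separate levels are uncertain. Adjusted p values were 3.89e-05, 5.31e-05, 7.82e-05 and 5.31e-05 in the order named (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). With total counts in place of TMM the higher share of calls was 56.9% in place of 45.9%, and the median log2 fold change of all tested models was 0.18 in place of 0, so the direction of the imbalance rests on the scaling. Fitted with stem and leaf alone the counts were 2068 higher and 2428 lower, and by limma-voom with a variance weight per tissue 2345 and 2606. Without stem replicates 1 and 2 they were 783 and 795 higher and 818 and 798 lower, and without leaf replicates 1 and 2 they were 681 and 684 higher and 928 and 930 lower.

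Root differed from stem and from leaf in more models than stem and leaf differed from each other. Against root, 4117 models were higher and 2880 lower in stem (36.6% of those tested), and 4349 were higher and 3390 lower in leaf (40.5%). In the root libraries evm.model.Chr13.1458-gene (chromosome 13) had 0 counts, and it stood at 20.2 ± 2.75 FPKM in stem and 79.5 ± 0.887 in leaf (n = 2 each), at least 208-fold and at least 814-fold above root. Also at 0 counts in root, evm.model.Chr04.1324-gene was at 11.2 ± 0.0686 FPKM in stem, at least 187-fold higher, and evm.model.Chr09.1885-gene was at 194 ± 6.81 FPKM in leaf, at least 1720-fold higher. Without root replicate 1 the bounds of evm.model.Chr13.1458-gene fall to 56.5 for stem and 221 for leaf, that of evm.model.Chr04.1324-gene to 50.9 and that of evm.model.Chr09.1885-gene to 469.

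On the root side, evm.model.Chr14.529-gene was at 146 ± 75.1 FPKM with 0 counts in stem and in leaf, at least 5240-fold and at least 5940-fold above them, or 2860-fold and 3250-fold without root replicate 1. With 0 counts in stem, evm.model.Chr10.389-gene was at 830 ± 771 FPKM in root, at least 4220-fold higher, a bound that is 9990 without root replicate 1 and 2070 without root replicate 2. With 0 counts in leaf, evm.model.Chr11.1270-gene was at 732 ± 128 FPKM in root (n = 2), at least 5780-fold higher, and it was at 11.2 FPKM in stem. Because the floor is fixed, leaving out stem replicate 1 or 2 lowers the bounds against stem to 2550 or 2690 for evm.model.Chr14.529-gene and 2050 or 2170 for evm.model.Chr10.389-gene, and leaving out leaf replicate 1 or 2 lowers those against leaf to 2940 or 3000 for evm.model.Chr14.529-gene and 2860 or 2920 for evm.model.Chr11.1270-gene. Adjusted p values of the stem comparison were 2.45e-05, 5.31e-05, 5.58e-05 and 5.15e-05 for evm.model.Chr13.1458-gene, evm.model.Chr04.1324-gene, evm.model.Chr14.529-gene and evm.model.Chr10.389-gene (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). In the leaf comparison the named models had adjusted p values between 4.47e-06 and 0.000387 by the same edgeR test with Benjamini-Hochberg adjustment. The median log2 fold change of all tested models was 0.19 for stem against root, and 0.05 with DESeq2 size factors. With the length trend removed, the higher share of calls was 49.2% in place of 58.8% for stem and 48.6% in place of 56.2% for leaf, so which side had more calls rests on that step.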

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

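The limma-voom fit, the fit without the length trend, and the fits without both bud or both root libraries were chosen after seeing the data; the other alternatives were fixed before. Counts kept within 1.5 times of the reported ones under every alternative for genes differing among tissues (12713 to 16067, and 14018 to 17015 with one library left out), root enrichment (763 to 1496; 893 to 1218), floral against vegetative tissues (3170 to 6670 higher and 3343 to 5958 lower; 4331 to 4629 and 3598 to 4288), stem against root (3039 to 4885 and 2246 to 3641; 3070 to 4535 and 2294 to 3103) and leaf against root (3378 to 5032 and 2635 to 4333; 3623 to 4729 and 2578 to 3629). Of 664 values of named models under alternatives, 655 kept direction and threshold, 9 kept direction and lost the threshold, and 0 reversed; the 9 all belong to the petal model.

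The other counts moved as follows. The adjusted p of 0.01 left 180 models enriched in stem, 290 in bud, 10 in petal and 17 in labellum; bud against open floral organs then had 1518 higher, labellum against petal 134 higher and 76 lower, and stem against leaf 810 higher and 999 lower. DESeq2 gave 82 petal-enriched models and 706 higher and 700 lower in labellum against petal. The limma-voom fit gave 89 petal-enriched models, 1492 higher and 631 lower for bud against open floral organs, 801 and 765 for labellum against petal, and 2345 and 2606 for stem against leaf. Fitting only the compared tissues gave 610 and 494 for labellum against petal and 2068 and 2428 for stem against leaf; both it and the limma-voom fit keep the variable bud and root libraries from setting the spread of other tissues. Leaving out both bud libraries gave 844 higher and 709 lower for labellum against petal and, with fewer tissues to exceed, 526 stem-, 225 petal- and 146 labellum-enriched models; leaving out both root libraries gave 479, 76 and 79. Without the fold minimum 97 models were enriched in petal, 2332 were lower in bud and 489 lower in labellum, as a wider criterion must give. Limma on log2(FPKM + 1) called 564 stem-enriched models and total counts 25 petal-enriched ones; the cause was not tested. The number of models with tau of at least 0.8, 1353, was 826 with a pseudocount of 0.1, 2257 with an FPKM filter of 0.1 and 3625 on linear FPKM.

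With one library left out in turn, and the lone library of its tissue assumed to vary like the others, enriched models ranged from 170 to 389 in stem, 412 to 906 in leaf, 287 to 857 in bud, 6 to 110 in petal and 16 to 77 in labellum. Called models ranged from 1883 to 3016 higher and 989 to 2568 lower for bud against open floral organs, 78 to 831 and 61 to 714 for labellum against petal, and 681 to 1663 and 798 to 1975 for stem against leaf. The tau count ranged from 1366 to 1564. Fewer libraries entered each of these fits, which does not account for the counts that rose with a bud library left out. Bud had the lowest variance weight in the limma-voom fit (0.173, against 3.015 in stem). Beyond these values, and for DESeq2, the cause was not tested. Models detected per tissue stayed within 1.5 times in every alternative, though the order of the tissues changed.

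The replicate numbers showed no pairing that runs through all tissues. Of the 15 pairs of tissues, 1 had a correlation of replicate differences above 0.1 (0.117 for bud and petal), and bud and labellum had -0.30. The 12 pairs that are not both floral gave -0.028 to 0.007, so a link among floral libraries is not excluded. With the replicate number as a block, 14875 genes differed among tissues, and 4540 were higher and 3963 lower in floral tissues. Labellum against petal then had 296 and 247, and every count stayed within 1.5 times. Such a block pairs libraries of the same number, so it cannot test the link of opposite sign between bud and labellum. The reported fit takes those libraries as independent. For floral against vegetative tissues the fit of the compared tissues is the reported fit itself, and the alternatives for gene lists were not run, as no list could be matched. With counts thinned to 5289212 per library, models with 10 or more counts in both libraries fell from 13959 to 13412 in root, 16839 to 14600 in stem, 16511 to 14134 in leaf, 16436 to 13785 in bud, 15746 to 13278 in petal and 15844 to 13401 in labellum.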

Other observations

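The patterns here were noticed in the data before they were tested, and the tests of a mislabelled bud library and of a shared difference between bud and labellum libraries were chosen only after related values had been seen.

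Enriched models with consecutive numbers on a chromosome were often enriched in the same tissue. The longest run held 6 stem-enriched models in a row, numbers 1196 to 1201 on chromosome 15, which include the model named for stem, evm.model.Chr15.1200-gene. Bud had a run of 5 on chromosome 13 (1262 to 1266) and runs of 4 on chromosomes 6 (2492 to 2495) and 9 (140 to 143), the last close to the model named for bud, evm.model.Chr09.138-gene. Root had runs of 4 on chromosomes 5 (707 to 710) and 11 (40 to 43), and labellum a run of 4 on chromosome 10 (567 to 570), while leaf and petal had none of that length.

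Among 13435 pairs of tested models with consecutive numbers, 215 were enriched in the same tissue, against 85.4 when tissue assignments were permuted (ratio 2.52, one-sided permutation p = 0.001, the smallest that 1000 permutations can give). The ratio was 2.42 for root, 4.80 for stem, 1.83 for leaf and 2.71 for bud, each with the same permutation p; labellum had 8 pairs against 0.06 (permutation p = 0.001) and petal 1 pair (permutation p = 0.0639). With all tissues together the ratio declined with distance, from 1.65 at 2 to 5 numbers apart. It was 1.30 at 20 apart (permutation p = 0.005) and 1.11 at 50 apart (permutation p = 0.168). Some excess thus remained at 20 apart, well beyond direct neighbours. One gene annotated as a pair of adjacent models would confine the excess to direct neighbours, and the ratio of 1.65 beyond them argues against that as the whole cause. Among neighbours whose lengths differ by more than 10% the ratio was 1.70 (129 pairs against 75.7). This argues against reads shared between copies of equal length as the whole cause. It cannot speak to copies of unequal length, since length does not measure how alike the sequences are. For neighbours within 10% in length there were 86 pairs against 9.69. Shared reads and tandem families of genes expressed in one tissue both remain open, since no sequence or gene name was used here.

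Short models were relatively higher in the floral libraries, with a rho of -0.350 between coding length and log2 fold change. The trend does not rest on a few abundant short transcripts, since rho was -0.354 without the 100 most abundant models of any library, or on one tissue, since its weakest value with a tissue left out was -0.330 (without bud). It was not confined to tissue-specific models, with a rho of -0.539 in the 9230 models with tau under 0.3, but tau comes from the same tissue means, so that value does not decide for or against a length bias of the RNA or the libraries that acts on every gene. Trends within the floral class, at one seedling age (0.271 for labellum against petal and -0.191 for bud against the open organs), cannot come from a difference between the classes. For the trend between them, organ class and seedling age change together, and any difference in RNA quality, collection or library preparation would follow the same line, so technical and biological sources remain open.

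The bud libraries differed 2.32 times as much as the labellum libraries and 1.65 times as much as the root libraries, the next most variable pair but the shallowest (robust SD of log ratios between replicates). Depth is argued against by a ratio of 2.21 to labellum and 1.56 to root with all libraries thinned to one total. Without the 100 most abundant models of any library the ratios were 2.33 and 1.68. The robust SD comes from a median over models, which leaving out so few can hardly move, so that step could not test the part of abundant models. The rho of bud replicate 2 was only 0.00449 higher with bud replicate 1 than with petal replicate 1. However, 100 models were at 20 CPM or more in bud replicate 1 and under 1 CPM in petal and labellum. In bud replicate 2 they stood at a median of 50.6% of that level. The 58 models chosen the same way from bud replicate 2 stood in bud replicate 1 at a median of 138.4%. These levels argue against a whole petal or labellum library under a bud label. They do not speak to a bud library of mixed tissue, since both sets were lower in bud replicate 2. The difference between the bud libraries was correlated across genes with that between the labellum libraries (r = -0.30), with 0.117 for bud and petal and 0.013 for petal and labellum, while the 12 pairs of tissues that are not both floral gave -0.028 to 0.007. A difference between plants, stages or collections that bud and labellum have in common may contribute, but the value for petal and labellum gives no support to one that runs through all 3 floral tissues.

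For floral against vegetative tissues, 8611 models were called, and the highest count among the 9 other splits of the 6 tissues into 3 and 3 was 5696; 1 of the 10 splits reached the real count, and 10 splits are too few to give a share under 0.05. In a simpler fit with the 12 libraries in 2 groups of 6, the real split called 7360 models and the highest of the other splits drawn called 10, so that 1 of 100 splits reached the real count. That share was meant to test chance but cannot, because the libraries come in pairs per tissue: 98 of the 99 other splits part at least 1 such pair, which puts tissue differences inside their groups, and the 1 that keeps the pairs together called 3 models.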
